A study of Homo sapiens with 6 samples.

How the data were processed

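The series measured RNA in U251, a human glioma cell line, after lentiviral delivery of a short hairpin RNA (shRNA), a small RNA that directs the degradation of a matching transcript. One group received a control hairpin (shCtrl) and the other a hairpin against CPVL (shCPVL), which encodes a serine carboxypeptidase. Each group held 3 arrays, named by group and replicate number as in the labels. Per the labels' protocols, total RNA was extracted with Trizol and biotin-labelled with an Affymetrix 3' in vitro transcription kit, a protocol that primes from the 3' end of polyadenylated RNA. The labels do not say whether the replicates of a group were separate cultures, so p-values measure the spread between these arrays, which may be technical. The labels name no scan dates, slides or other batches.

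The authors deposited log2 expression values for 49395 probe sets, made with RMA per the submitters' processing notes. RMA corrects the background, forces the same distribution of values on all arrays and summarises the probes of a probe set. Its version and the genome build were not given in the sources used here. The equalised distributions mean that each change is relative to the bulk of the probe sets on the same array, and a general rise or fall of RNA content cannot be seen. Background signal and saturation both compress log2 differences, so folds of dim and very bright genes tend to be understated. The array medians lay between 6.85 and 6.87, and no 2 arrays held identical values. The number of arrays limits the precision.

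The authors also deposited a table of their own comparison, with an unadjusted p-value, an FDR, a log2 fold change, a linear fold and a signed fold score per probe set. Per the file headers it compares knockdown with control. Its log2 fold changes equalled the differences of the group means, and its p-values differed by at most 0.011 in log10 from limma with an intensity trend. This table gave the Entrez gene identifier and the alignment of each probe set, without symbols and without naming the build of its coordinates. Symbols were looked up by Entrez identifier in an NCBI RefSeq gene table of the assembly GRCh38.p14, which was used for names only.

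Of the probe sets, 102 were array controls. Of the others, 46869 had exactly 1 Entrez identifier, 1994 had several and 430 had none, and 46726 of those with exactly 1 received a symbol while 143 did not. The plan written before the data were examined spoke of exactly 1 gene symbol; since the deposited table holds no symbols, exactly 1 Entrez identifier was required. Each gene was represented by its probe set with the highest mean over all 6 arrays, which left 18712 genes, with no filter on low values.

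The design, the alternatives, 26 gene lists and the rule for naming genes were fixed before the data were examined, except where stated. Differences are shCPVL minus shCtrl. Genes were tested in R 4.3.3 with limma 3.58.1 (lmFit and eBayes without trend, two-sided), and p-values were adjusted by Benjamini-Hochberg over all 18712 genes. A gene was called at an adjusted p under 0.05, and counts were given again with a fold of at least 1.5. "Rose" and "fell" refer to called genes. Single values such as CPVL and the control probe sets were also compared by a two-sided exact permutation test, which cannot go below 0.1 with 3 against 3 arrays. Errors are SD over 3 arrays unless a standard error (SE) is named.

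The lists comprised 20 pathway and axis lists and 6 lists of cell type markers with 583 genes, of which 579 were measured. USP18, SOD2, CYP51A1 and SLC2A3 were represented only by probe sets with several identifiers. Lists were tested with camera at a preset correlation of 0.01 between genes, adjusted over the 20 lists and separately over the 6. Camera asks whether a list moved more than the other genes. It was run again with the correlation estimated from the arrays, beside the self-contained test fry, and counts of changed members were also adjusted over the list alone.

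The text names CPVL and its relatives CTSA and SCPEP1, all axis members, the 12 highest and 12 lowest log2 changes among called genes whose groups did not overlap, and up to 4 members per list with the greatest called change (up to 2 where none was called). Some genes that this rule takes are not reported here. Other named genes are marked as chosen after their values were seen. Of the 119 genes taken by the rule, 97 had several probe sets, and for 1 of them (MGP) another probe set was called in the opposite direction.

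The alternatives were another quantile normalization, centring on the array median, a replicate block, eBayes with trend or robust and array weights. Further ones were the mean or median of a gene's probe sets, exclusion of probe sets with the suffix x_at or s_at, and 2 filters on low values. The last were the removal of each array in turn, a test against a minimum fold of 1.2 (treat), a test without moderation and single probe sets. On simulated data with the measured spread, the gene test recovered 22 of 50 genes changed by 0.3 log2 units, 47 of 50 at 0.585, 49 of 50 at 1 and 50 of 50 at 2, with 5 false calls among 18712 genes. Camera called the simulated list shifted by 0.2 and 0 of 20 unshifted lists. The simulated genes were drawn independently, so this could not test how camera behaves when the genes of a list are correlated. Far fewer genes were changed in the simulation than were called in the data. Figures were drawn with matplotlib 3.10.9.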

Results

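Transcripts of U251 glioma cells carrying a control hairpin were compared with those of U251 cells carrying a hairpin against CPVL, to find the genes whose expression differs when CPVL is reduced. Expression was measured on 6 arrays, 3 per group, as log2 RMA values for 18712 genes. Arrays of the same group correlated at 0.9974 to 0.9986 over all probe sets and arrays of different groups at 0.9918 to 0.9930. The first principal component separated the groups and held 69.9% of the variance.

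CPVL, a serine carboxypeptidase with sequence similarity to lysosomal protective protein, was lower in all 3 shCPVL arrays than in any shCtrl array. Its log2 value was 8.27 ± 0.11 (SD, n = 3) in shCtrl and 7.28 ± 0.09 (SD, n = 3) in shCPVL, a change of −0.99 (SE 0.07, limma adjusted p = 8.3e-05). The transcript signal remaining was 50.5% of the control, with a 95% confidence interval of 44.9% to 56.7%. The exact permutation test gave p = 0.1, the smallest that 3 against 3 arrays allow. A single probe set represented CPVL (Entrez 54504), aligned to chromosome 7 from 29034848 to 29186153 on the minus strand in the authors' deposited table, whose build is not named. Of its human relatives, CTSA, which encodes cathepsin A, rose by 0.39 (SE 0.05) from 10.67 ± 0.02, and SCPEP1 was at 8.90 ± 0.03 in shCtrl and 8.85 ± 0.06 in shCPVL, a difference within the spread of the arrays (adjusted p = 0.65).

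**Figure D1:**
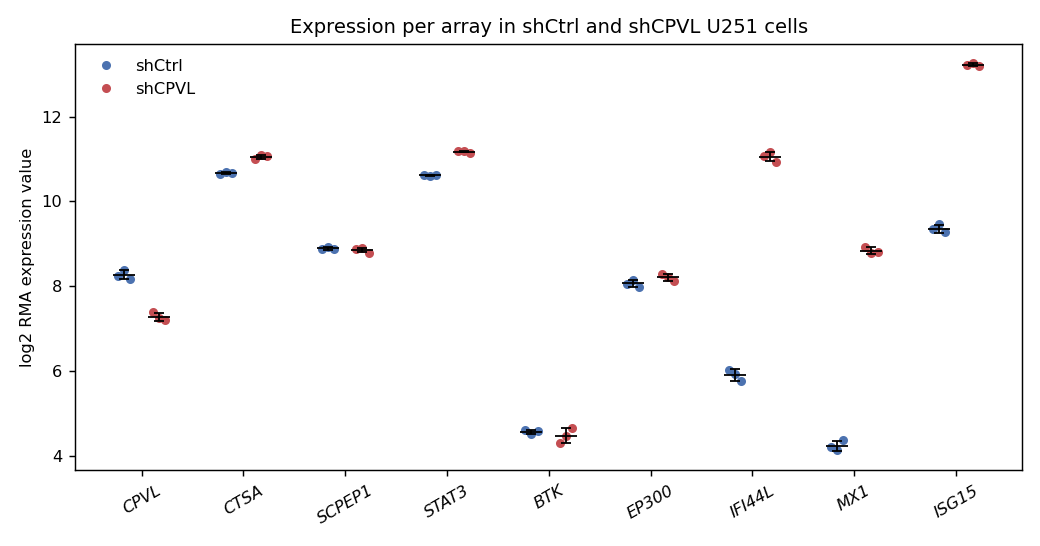
Log2 RMA value of 9 genes on each of the 6 arrays; blue points are the 3 shCtrl arrays, red points the 3 shCPVL arrays, and black marks the mean with SD. CPVL was at 8.27 in shCtrl and 7.28 in shCPVL, whereas the interferon-stimulated genes IFI44L and ISG15 were 35.6-fold and 14.7-fold higher in shCPVL.

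Across the transcriptome, the strongest increases belonged to interferon-stimulated genes, while the decreases were smaller and included genes of DNA replication and cholesterol synthesis. Of 18712 genes, 3757 (20.1%) changed, 1581 higher and 2176 lower in shCPVL. With a fold of at least 1.5 there were 470 genes, 228 higher and 242 lower. At a fold of at least 2 there were 83 higher and 40 lower, and at a fold of at least 4 there were 27 higher and 0 lower. The groups did not overlap in 6721 genes, where chance gives 10% of the genes tested. The count without a fold limit depended on single arrays, with 2438 genes without shCtrl replicate 1 and 2380 without shCPVL replicate 2, and it reached 9761 with array weights, whereas the count with a fold of at least 1.5 stayed between 471 and 488 when any array was left out. The balance of directions at that fold was not stable, with 242 higher and 224 lower after another quantile normalization and 256 and 215 without shCPVL replicate 3.

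**Figure D2:**
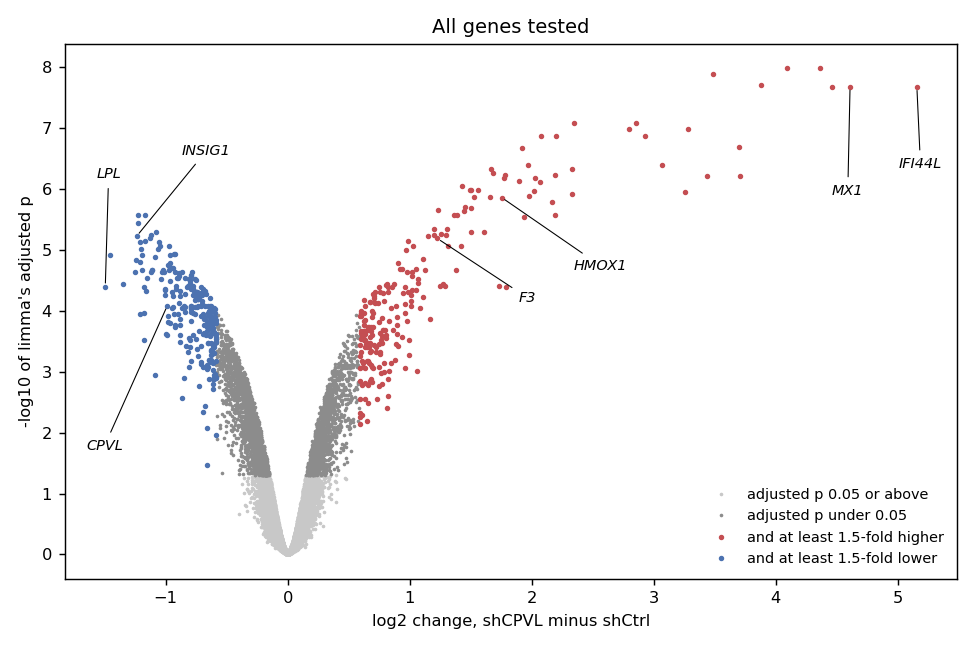
Each point is a gene, with its log2 change (shCPVL minus shCtrl) on the x axis and −log10 of limma's adjusted p on the y axis; red and blue points passed an adjusted p of 0.05 with a fold of at least 1.5. The right arm holds 228 genes and reaches a log2 change of 5.16 at IFI44L, and the left arm holds 242 genes and ends at −1.49 at LPL.

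Interferon-stimulated genes rose nearly throughout. Of 45 measured members, 42 rose and 0 fell, with a median log2 change of 1.89, and 42 rose and 1 fell when adjusted over the list alone (camera adjusted p = 4.1e-60; adjusted p = 0.014 with an estimated correlation). IFI44L rose from 5.90 ± 0.14 to 11.05 ± 0.11 (35.6-fold), MX1, a GTPase that blocks viral replication, from 4.23 ± 0.12 to 8.84 ± 0.08, IFI6 from 8.76 ± 0.14 to 13.22 ± 0.02 (22.0-fold) and IFITM1, a membrane protein that restricts viral entry, from 8.06 ± 0.08 to 12.42 ± 0.03 (20.6-fold). The other 8 of the 12 highest changes were IFIT1 (17.1-fold), the ubiquitin-like modifier ISG15 (14.7-fold), IFIT3 (13.1-fold), MX2 (8.69 ± 0.13 in shCPVL), IFI27 (11.2-fold), DDX60 (10.8-fold), the cytosolic RNA sensor RIGI (9.72-fold) and OAS1 (9.53-fold), with adjusted p up to 1.1e-06 (OAS1). MX1 and MX2 in shCtrl lay close to the background probe sets, which had a median of 3.59 and a mean of 4.95 there, so no fold is given for them. The 3 members that did not pass over all genes were IRF7 (−0.15), CMPK2 (0.14) and EPSTI1 (0.03), named after their values were seen, and IRF7 was the member that fell over the list alone. EPSTI1 and IRF7 were dim, at 4.88 and 5.60 in shCtrl, so a small change of them may not be visible.

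Of the list of antigen presentation genes and interferon gamma targets, many members rose as well. Of 27 members, 17 rose and 0 fell (20 and 0 when adjusted over the list alone), with a median change of 0.47 (camera adjusted p = 3.3e-16; adjusted p = 0.014 with an estimated correlation). HLA-F rose by 2.19 (SE 0.09), the guanylate-binding protein gene GBP1 by 1.94 (SE 0.08), the immunoproteasome subunit gene PSMB9 by 1.92 (SE 0.05) and the peptide transporter gene TAP1 by 1.78 (SE 0.05). With the median of its probe sets the change of HLA-F was 0.38. Over all genes, 10 members did not pass. Among them were CIITA (−0.02), CD74 (−0.11), HLA-DRA (−0.03), HLA-DMA (−0.16), CXCL9 (−0.03) and IDO1 (0.17), named after their values were seen. The others were HLA-G (0.25), SOCS1 (0.23), CXCL11 (0.19) and PSMB10 (0.03). CXCL10 rose by 0.69 from 4.48 in shCtrl. These too were named after their values were seen. HLA-DRA, HLA-DMA, CXCL9, CXCL11 and IDO1 were dim, at most 5.51 in shCtrl, as was SOCS1 at 5.59. The hybridisation control probe sets, which read bacterial RNA added before hybridisation, were also higher in shCPVL, by 0.31 on average and by at most 0.41.

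A list of 12 signalling genes that includes BTK, the p300 gene EP300 and the knockdown target itself was tested as an axis. STAT3 rose by 0.56 (SE 0.04), as did SOCS3, a feedback inhibitor of cytokine signalling, by 0.57 (SE 0.07). BTK, at 4.56 ± 0.05 in shCtrl and 4.47 ± 0.18 in shCPVL, and EP300, at 8.06 ± 0.09 and 8.21 ± 0.08, did not pass (adjusted p = 0.60 and 0.19). BTK lay below the mean of the background probe sets (4.95 in shCtrl and 4.91 in shCPVL), so a change of BTK may not be visible. JAK1 (0.17), JAK2 (0.17), PTPN6 (0.05), PIAS1 (0.03), TYK2 (−0.00) and CREBBP (−0.05) did not pass either, although JAK1 passed under several alternatives, among them another quantile normalization (0.19). With array weights BTK (−0.13), EP300 (0.16), JAK1 (0.20) and JAK2 (0.15) passed. That setting called 9761 of all 18712 genes and rested mostly on shCtrl replicate 1 and shCPVL replicate 2, so passing there says little. The list, with 3 of 12 members higher and 1, CPVL itself, lower (4 and 1 over the list alone), had a camera adjusted p of 0.021. That call was lost with an estimated correlation (adjusted p = 0.36) and when members of the interferon and antigen lists were taken out of the other lists (adjusted p = 0.14), an alternative chosen after the data were seen.

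Genes of DNA replication, mitosis and homologous recombination fell. Of 34 replication genes, 31 fell and 0 rose (32 and 0 when adjusted over the list alone; median −0.46), led by the cyclin gene CCNE1 (−0.85, SE 0.06), GINS4 (−0.82, SE 0.05), the thymidylate synthase gene TYMS (−0.79, SE 0.04) and MCM10 (−0.70, SE 0.05). Of 35 mitotic genes, 25 fell and 0 rose (31 and 0 over the list alone; median −0.31), among them the kinase gene PLK1 (−0.68, SE 0.06), BIRC5 (−0.62, SE 0.05), FOXM1 (−0.58, SE 0.06) and CENPE (−0.54, SE 0.05). Of 22 recombination and Fanconi genes, 14 fell and 0 rose in both adjustments (median −0.29), among them EXO1 (−0.53, SE 0.07), FANCD2 (−0.47, SE 0.05) and BRCA1 (−0.46, SE 0.06). Camera gave adjusted p = 1.4e-21, 1.5e-15 and 1.3e-07. With an estimated correlation none of these 3 calls held (adjusted p = 0.094, 0.081 and 0.22). Without the x_at and s_at probe sets (here called shared probe sets), the changes of CCNE1, GINS4 and FANCD2 were −0.41, −0.28 and −0.31. With the median of its probe sets that of FOXM1 was −0.37. The hybridisation controls were higher by 0.31. Since RMA equalises the distributions, their sign does not tell which way a processing difference would move these genes.

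Cholesterol synthesis genes also fell. Of 24 measured members, 15 fell and 0 rose (16 and 0 when adjusted over the list alone; median −0.28; camera adjusted p = 1.9e-08; adjusted p = 0.081 with an estimated correlation). INSIG1, a sterol sensor of the endoplasmic reticulum, fell from 10.58 ± 0.07 to 9.35 ± 0.05, and MSMO1 fell by 0.94 (SE 0.07). INSIG1 was also among the 12 lowest changes of all genes. The lowest were the lipoprotein lipase gene LPL (−1.49, SE 0.10), the engulfment receptor gene MEGF10 (−1.46, SE 0.07) and NOG, which encodes the BMP antagonist noggin (−1.35, SE 0.08). ATPAF1 (−1.25), TMX4 (−1.24), RAD23B (−1.23), PMEPA1 (−1.23), MGP (−1.21), the proteoglycan gene VCAN (−1.21), the cholesterol ester hydrolase gene NCEH1 (−1.21) and IMPDH1 (−1.20) completed these 12, with adjusted p up to 1.1e-04 (MGP). MGP was dim, at 5.94 in shCtrl, and its other probe set was called in the opposite direction (0.35). The other probe set of MEGF10 was not called (−0.04), and those of TMX4 changed by −0.40 and −0.31. Of the 5 ATPAF1 probe sets 3 were called, and the others changed by −0.07 and −0.54.

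Several stress-related lists were higher as sets, with smaller changes, in the arrays in which the hybridisation controls were higher by 0.31. Of 24 ATF4 and amino acid response genes, 13 rose and 2 fell in both adjustments (median 0.22; camera adjusted p = 1.8e-05; adjusted p = 0.23 with an estimated correlation), including NUPR1 (0.63, SE 0.09), the asparagine synthetase gene ASNS (0.63, SE 0.05) and both subunits of the cystine transporter, SLC7A11 (0.63, SE 0.06) and SLC3A2 (0.63, SE 0.05). Of 16 NRF2 antioxidant genes, 8 rose and 2 fell (12 and 2 when adjusted over the list alone; camera adjusted p = 1.3e-04; adjusted p = 0.081 with an estimated correlation). HMOX1, which encodes the inducible heme oxygenase, rose from 8.41 ± 0.11 to 10.17 ± 0.01 (3.37-fold), NQO1 by 0.36 (SE 0.04) and TXNRD1 by 0.33 (SE 0.05).

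Of 25 p53 targets, 10 rose and 4 fell (11 and 5 over the list alone; camera adjusted p = 0.0084; adjusted p = 0.36 with an estimated correlation). BTG2 rose by 0.82 (SE 0.05), SESN2 by 0.60 (SE 0.05), SESN1 by 0.58 (SE 0.06) and the cyclin-dependent kinase inhibitor gene CDKN1A by 0.51 (SE 0.05); without shared probe sets BTG2 rose by 1.24. Of 29 apoptosis regulators, 11 rose and 1 fell (12 and 1 over the list alone; camera adjusted p = 2.7e-04; adjusted p = 0.081 with an estimated correlation). Members that rose act in different directions in cell death. BIRC3, an inhibitor of apoptosis, rose by 0.75 (SE 0.09), the death ligand gene TNFSF10 by 0.57 (SE 0.07) and the BH3-only gene BBC3 by 0.47 (SE 0.06). Of the p53 list, 6 genes also stood in other lists.

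Of 22 YAP/TAZ targets, 10 rose and 2 fell (12 and 2 over the list alone; camera adjusted p = 2.7e-04; adjusted p = 0.22 with an estimated correlation). The tissue factor gene F3 rose by 1.23 (SE 0.06), GADD45B by 0.85 (SE 0.05) and the ectonucleotidase gene NT5E by 0.58 (SE 0.08). DOCK5 fell by 0.76 (SE 0.05), a call lost when the median of its probe sets was used (−0.03), with which GADD45B rose by 0.47. Of 32 lysosomal genes, 12 rose and 2 fell (13 and 2 over the list alone; median 0.09; camera adjusted p = 0.0026; adjusted p = 0.37 with an estimated correlation). Besides CTSA, the protease gene CTSD rose by 0.35 (SE 0.05), TPP1 by 0.34 (SE 0.04) and the autophagy receptor gene SQSTM1 by 0.31 (SE 0.05); the call of TPP1 was lost with the median of its probe sets (0.11), and SQSTM1 rose by 0.51 without shared probe sets.

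The other 7 pathway lists did not pass camera, and each held members that rose and members that fell. Without shared probe sets, 2 of them were called lower, the endoplasmic reticulum stress list (adjusted p = 0.010; 0.0043 to 0.83 over its alternatives) and the MYC and ribosome biogenesis list (adjusted p = 0.034; 0.020 to 0.60). Of 24 endoplasmic reticulum stress genes, 6 rose and 9 fell (7 and 13 over the list alone; median −0.13; adjusted p = 0.39). The greatest changes were those of DDIT3 (0.66, SE 0.09), CHAC1 (0.56, SE 0.08), DNAJB9 (0.51, SE 0.08) and ATF3 (0.50, SE 0.06), which rose. Among those that fell were SEL1L (−0.41, SE 0.05), HYOU1 (−0.40, SE 0.05) and MANF (−0.36, SE 0.04), named after their values were seen; the call of SEL1L was lost with the median of its probe sets (−0.14), and HYOU1 fell by 0.25 with their mean. Of 25 NF-kB and cytokine genes, 3 rose and 3 fell in both adjustments (adjusted p = 0.12). TNFAIP3, a feedback inhibitor of NF-kB, rose by 0.99 (SE 0.11), while the cytokine genes CXCL8 (−0.60, SE 0.06) and LIF (−0.41, SE 0.05) fell. Of 39 matrix and mesenchymal genes, 6 rose and 6 fell (7 and 6 over the list alone; adjusted p = 0.56), with a median of 0.03 and a mean of −0.03. N-cadherin, encoded by CDH2, fell from 10.41 ± 0.03 to 9.29 ± 0.05, MMP2 fell by 1.04 (SE 0.05) and PLAU by 0.73 (SE 0.05), and COL1A2 rose by 0.45 (SE 0.04). Without shared probe sets TNFAIP3 rose by 0.56 and COL1A2 by 0.24.

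Of 22 immediate early and MAPK feedback genes, 5 rose and 6 fell (5 and 7 over the list alone; adjusted p = 0.72). The phosphatase genes DUSP5 (0.85, SE 0.06) and DUSP1 (0.69, SE 0.06) rose, and ETV5 (−0.76, SE 0.06) and DUSP6 (−0.65, SE 0.06) fell. Of 28 hypoxia and glycolysis genes, 4 rose and 5 fell (5 and 5 over the list alone; adjusted p = 0.89), with EGLN3 higher (0.90, SE 0.09) and ENO2 (−0.79, SE 0.06), LDHA (−0.53, SE 0.05) and ANKRD37 (−0.53, SE 0.05; −0.26 with the median of its probe sets) lower. Of 23 MYC and ribosome biogenesis genes, 1 rose and 6 fell (1 and 7 over the list alone; adjusted p = 0.16). MYC itself rose by 0.29 (SE 0.05), and DKC1 (−0.43, SE 0.05), BOP1 (−0.31, SE 0.05) and CAD (−0.29, SE 0.05) fell. Of 23 oxidative phosphorylation genes, 1 rose and 4 fell (1 and 5 over the list alone; adjusted p = 0.78).

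**Figure D3:**
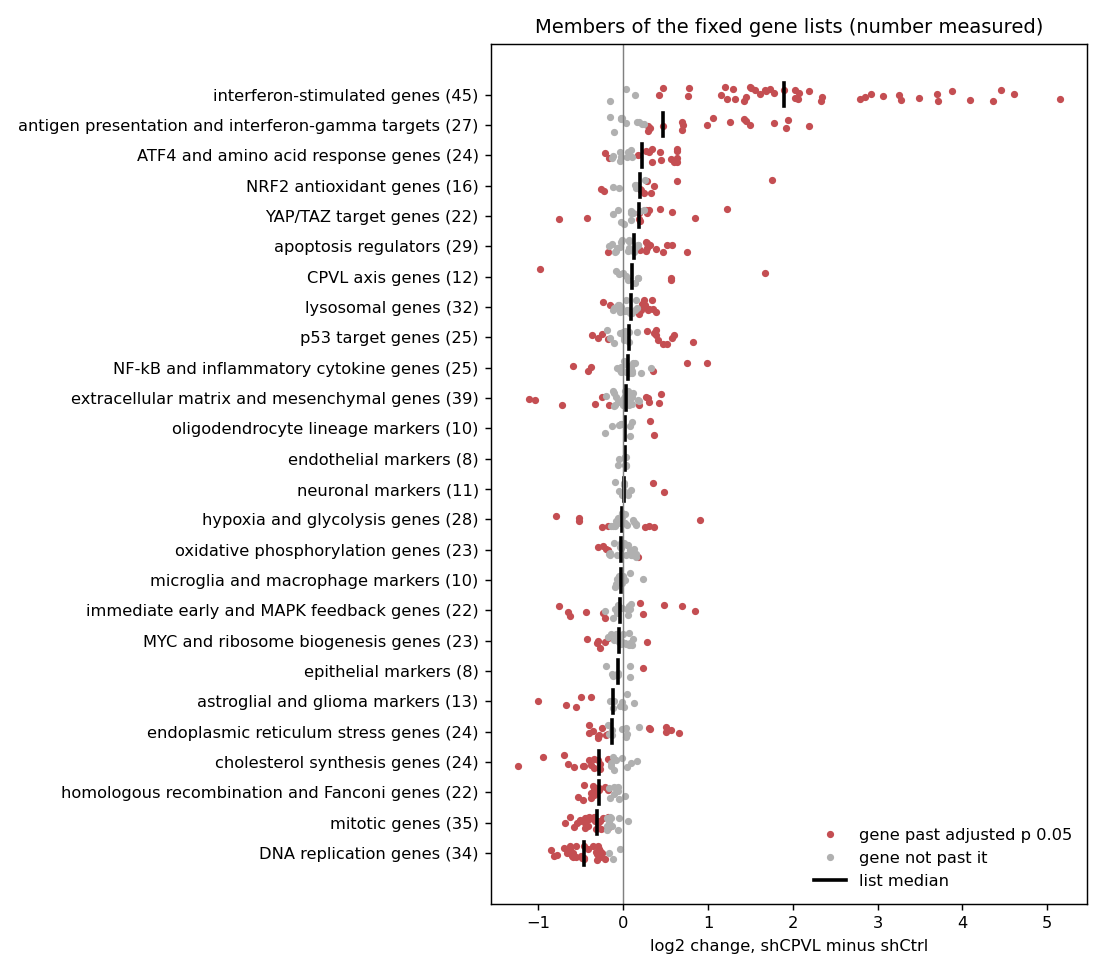
Log2 change (shCPVL minus shCtrl, x axis) of each measured member of the 26 fixed lists, ordered by list median (black bar); red points passed an adjusted p of 0.05 over all genes and grey points did not. The interferon-stimulated genes had the highest median (1.89) and the DNA replication genes the lowest (−0.46).

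Markers of astroglial cells and glioma fell in part, and few markers of other cell types passed the test. Of 13 astroglial and glioma markers, 5 fell and 0 rose in both adjustments (camera adjusted p = 0.0053; adjusted p = 0.15 with an estimated correlation). GFAP, the intermediate filament of astrocytes, fell from 10.17 ± 0.11 to 9.17 ± 0.05 (2.01-fold), FABP7 by 0.68 (SE 0.04; 0.38 with the median of its probe sets), the glutamate transporter gene SLC1A3 by 0.56 (SE 0.07) and the connexin gene GJA1 by 0.49 (SE 0.05). Neither adjustment called a member of the 10 microglia and macrophage markers (median −0.03) or the 8 endothelial markers (median 0.02). In these lists the greatest differences were CD68 (0.23, adjusted p = 0.11), CX3CR1 (−0.09), CLDN5 (−0.06) and KDR (−0.05). CD68 passed with the mean or median of its probe sets (0.22) and with the dimmest 40% of genes left out. CLDN5 (−0.14) and KDR (−0.09) passed with array weights, under which 9761 of 18712 genes were called. Of 11 neuronal markers 2 rose, SYT1 by 0.48 (SE 0.08; 0.19 with the median of its probe sets) and NEFL by 0.36 (SE 0.09). The NEFL call was lost without any 1 array other than shCtrl replicate 3 (0.24 to 0.39), and NEFL turned to −0.13 without shared probe sets. Of 10 oligodendrocyte lineage markers PDGFRA (0.36, SE 0.04) and CNP (0.32, SE 0.06) rose, and of 8 epithelial markers KRT18 did (0.23, SE 0.05), all 3 unchanged in call over their list alone. The PDGFRA and KRT18 calls were lost with the median of a gene's probe sets (0.20 and 0.19), and that of KRT18 also without shCtrl replicate 1 (0.24) or shCPVL replicate 2 (0.23). The neuronal, oligodendrocyte, myeloid, epithelial and endothelial lists did not pass camera (adjusted p = 0.55, 0.55, 0.97, 0.97 and 0.97).

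RNA integrity, read as the difference between 3' and 5' control probe sets, did not separate the groups. The difference was 0.29 ± 0.05 (SD, n = 3) in shCtrl and 0.30 ± 0.02 (SD, n = 3) in shCPVL for ACTB (exact permutation p = 1), and −0.06 ± 0.02 and −0.06 ± 0.01 for GAPDH (exact permutation p = 0.7). All 18 hybridisation control probe sets were higher in shCPVL, by 0.16 to 0.41, with a mean of 10.74 ± 0.06 in shCtrl and 11.04 ± 0.10 in shCPVL (exact permutation p = 0.1). Of 24 poly-A control probe sets, 22 were higher, by 0.16 on average over the 24 (exact permutation p = 0.2). The ACTB control probe sets differed by −0.18 on average and those of GAPDH by −0.03 (exact permutation p = 0.1 for each).

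The authors' deposited table listed 11833 probe sets with an FDR under 0.05, 5231 higher and 6602 lower, and 1236 of them with an absolute fold of at least 1.5, 594 higher and 642 lower. At the level of probe sets, limma without trend called 9156. It called 1236 of the 1236 with that fold in the authors' deposited table (100%) and 8893 of the 11833 (75.2%), all in the same direction. Both rest on the same 6 arrays, so the overlap is no independent evidence.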

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

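Planned in this part were the counts over splits of the arrays and the group difference of the hybridisation controls. All its other tests were chosen after the results were seen.

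A probe set assigned to RAP1A, outside the gene comparison because RAP1A has a brighter one, showed the greatest change on the array. It was at 5.91 ± 0.03 (SD, n = 3) in shCtrl and 14.00 ± 0.02 (SD, n = 3) in shCPVL, a log2 change of 8.09, given as 272-fold in the authors' deposited table, where it has no alignment. The other 3 RAP1A probe sets, none of them called, had log2 changes of −0.10 to 0.26 with upper confidence limits of at most 0.59. They argue against a rise of RAP1A RNA of this size in all its transcripts. The brightest was called with array weights (0.51), under which 9761 of 18712 genes were called. Binding of another transcript measured elsewhere on the array stays open, since the highest other change was 5.16 and background can compress a change. RNA of the knockdown construct may be another source: the other 186 probe sets without an alignment had log2 changes no higher than 2.01, which decides nothing, and no probe or vector sequence was used here.

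The hybridisation controls, which lie outside the gene comparison, were 0.31 higher in shCPVL on average. A processing difference of that size as the source of the interferon-stimulated rise is argued against by the lower quartile of the 45 members, 1.32, which lies above the highest control probe set (0.41). For small changes it may contribute and cannot be told apart from the knockdown: 1127 of the 1581 genes called higher (71.3%) changed by no more than 0.41, as did 1527 of the 2176 called lower (70.2%), and all 18 control probe sets were higher in each shCPVL array than in any shCtrl array. The shares were alike in both directions, which does not tell whether such a difference contributed. Since RMA equalises the distributions, the sign of the controls does not tell which way such a difference would move a gene.

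The source of the rise of the interferon-stimulated genes stays open. Interferon made by the knockdown cells could itself follow from the loss of CPVL. Interferon beta RNA was tested with IFNB1, which differed by −0.0071 at a level of 3.91 in shCtrl. That level is too close to the background median of 3.59 to decide. Another interferon gene, IFNE, was called higher (0.72, SE 0.08), from a dim level of 4.93 in shCtrl. Whether it contributed was not tested. A reaction to the hairpin or its vector rather than to the loss of CPVL may also be the cause. It cannot be told apart from the loss of CPVL with 1 knockdown group. Another hairpin, a rescue of CPVL and secreted interferons were not analysed here.

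The 10 splits of the 6 arrays into 3 and 3 are too few for a share under 0.05. The real split called 3757 genes and the highest other 0, and with a fold of at least 1.5 it called 470 against 0. In each case 1 of the 10 splits gave as many, the real one. Each other split mixes both groups on each side, so the real group difference widens the spread within its sides. Its gene counts are therefore no baseline for chance, and nothing is concluded from the counts of 0. At an unadjusted p under 0.05 limma gave 5781 genes in the real split and 138 to 2167 in the other 9, where 936 of the genes tested are expected by chance. The split with 2167 set shCtrl replicates 1 and 3 and shCPVL replicate 3 against the other arrays. The second principal component, with 15.5% of the variance, also set these arrays apart from the others. A factor that crosses both groups was not tested. Camera with its preset correlation called 13 lists in the real split and 6 to 10 in the others, each of which keeps a part of the difference because it sets 2 arrays of one group and 1 of the other against the rest. With an estimated correlation it called 2 lists in the real split and 0 in each other, which for the same reason is no baseline for chance.

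Probe sets with no single named gene, which the comparison by gene left out, held fewer calls than the array as a whole: 324 of 2567 (12.6%) against 18.5% of all probe sets, 167 higher and 157 lower, with log2 changes from −1.33 to 3.25.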

How the results depend on the processing

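The control probe set alternatives and the lists without interferon and antigen genes were chosen after the data were seen; the other alternatives were planned. CPVL stayed called at −0.93 to −1.04 under each alternative. The hybridisation controls stayed at 0.26 to 0.36. The interferon-stimulated and antigen lists stayed called in all 20 alternatives each. Over 149 genes taken by the naming rule or chosen later, 2568 of 2647 alternatives left the call as it was, 47 lost it, 30 gained it and 2 turned the direction. NEFL turned to −0.13 without shared probe sets and IFNK, not called in the main comparison, to −0.15 with array weights. Over the 26 lists, 502 of 520 left the call as it was, 13 lost it, 4 gained it (the endoplasmic reticulum stress and ribosome biogenesis lists, lower by fry and without shared probe sets) and 1 turned it: the matrix list (median 0.027) was called lower by fry (adjusted p = 0.044; 0.044 to 0.80 over its alternatives). The cause was not tested for these changes.

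The total of 3757 called genes (1581 higher, 2176 lower) fell to 2380 to 3282 when an array was left out (949 to 1495 higher, 1431 to 1924 lower) and fewer samples entered the fit. It was lowest without shCPVL replicate 2 (2380) and shCtrl replicate 1 (2438). Each of these fits left out 1 array, so the number of samples does not account for the differences between them. The total rose to 9761 with array weights (3851 higher, 5910 lower). These gave shCPVL replicate 2 and shCtrl replicate 1 the weights 6.84 and 3.96 and no other array over 0.51. Single probe sets gave 9127 (3910 higher, 5217 lower) and, with a fold of at least 1.5, 1232 (590 higher, 642 lower) against 470 genes, since several probe sets can stand for a gene. A fold of at least 2 left 123 (83 higher, 40 lower). A test against a minimum fold of 1.2, in place of the 1.5-fold limit, gave 646 genes (274 higher, 372 lower). Of the 470 genes, 469 or 470 were also called when an array was left out. Lists called higher went from 9 to 2 and lists called lower from 4 to 0 with an estimated correlation, fry called 7 lower, and 6 were lower without shared probe sets. Of the probe sets past an FDR of 0.05 in the authors' deposited table, 75.2% passed in limma without trend, and 100% of those with a fold of at least 1.5 did. Apart from the reasons given, the cause of these shifts was not tested. The share of lower genes among those called without a fold limit was 57.9% and lay between 52.5% (another quantile normalization) and 62.4% (without shCtrl replicate 3).

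The replicate numbers did not pair the arrays: the deviations of same-numbered arrays correlated at −0.25, 0.09 and 0.22, and 1 of 3 shCtrl arrays correlated best with its own number. Those of shCtrl replicate 2 correlated at 0.36 with shCPVL replicate 1 and at −0.41 with shCPVL replicate 3. An unlabelled factor shared by arrays of both groups therefore stays possible and was not tested. With a replicate block, 3079 genes were called (470 with a fold of at least 1.5) and the same numbers of lists, 9 higher and 4 lower. Signal over background limits dim genes, for which a change cannot be read: the background probe sets had a median of 3.59 and ranged from 2.72 to 11.5 with their GC content.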

Other observations

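The genes in this part were chosen after their values were seen. SAMHD1, which limits the nucleotide supply of viruses, rose from 8.57 ± 0.07 to 10.54 ± 0.03 (SD, n = 3, 3.92-fold). The guanylate-binding protein genes GBP3 (0.96, SE 0.06) and GBP5 (0.78, SE 0.08), the RNA editing enzyme gene ADAR (0.72, SE 0.05) and CD274, which encodes the immune checkpoint ligand PD-L1 (0.78, SE 0.07; 0.51 with the mean of its probe sets), rose as well. Among interferon genes, IFNE rose from 4.93 ± 0.14 to 5.65 ± 0.06, while IFNB1 (−0.01), IFNA2 (0.03), IFNL1 (−0.03), IFNK (0.03) and IFNG (0.00) did not pass, at levels of at most 5.24 in both groups. IFNE in shCtrl lay near the mean of the background probe sets (4.95), so the size of its rise is uncertain. The receptor genes IFNAR1 (−0.28, SE 0.07) and IFNAR2 (−0.27, SE 0.05) fell. The call of IFNAR1 was lost without shCtrl replicate 1 or 2 or shCPVL replicate 2 (−0.26 to −0.23), and that of IFNAR2 without shared probe sets (−0.24). CGAS, which encodes a DNA sensor (0.16), and the adaptor genes STING1 (−0.10) and MAVS (−0.13) did not pass. All 3 passed with array weights (0.14, −0.09 and −0.15), under which 9761 of 18712 genes were called, and MAVS also with the median of its probe sets (−0.31).

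The lamin gene LMNB1 fell from 8.77 ± 0.13 to 7.59 ± 0.14 (SD, n = 3) and LMNB2 by 0.56 (SE 0.05), and LMNA rose by 0.20 (SE 0.05), a call that was lost without shCtrl replicate 1 or 3 or shCPVL replicate 1 or 2 (0.17 to 0.21) and held with the median of its probe sets (0.32). Of the TGF-beta receptor genes TGFBR2 rose by 0.67 (SE 0.05) and TGFBR1 fell by 1.16 (SE 0.08), the latter no longer called with the median of its probe sets or without shared probe sets (−0.34 in each). The growth factor gene PDGFC fell from 10.70 ± 0.04 to 9.69 ± 0.11, the hyaluronan synthase gene HAS2 from 6.28 ± 0.18 to 5.28 ± 0.07 and the adhesion gene NEGR1 from 8.14 ± 0.07 to 7.05 ± 0.31 (−0.65 with the median of its probe sets).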
